A study of Rattus norvegicus with 12 samples.

How the data were processed

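RNA from veins of male rats was measured on 12 single-colour Agilent arrays, 3 for each of 4 days. Days 7, 14 and 28 were times after an external jugular vein had been placed as a bypass in the carotid artery, and day 0 was vein from rats with no operation. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed, and transcripts were labelled with Cy3 along their whole length using oligo(dT) together with random primers. The series is described as non-coding RNA profiling, and the array carries probes for coding and for other transcripts. All arrays bear the same replicate number in the labels, so replicates are numbered 1 to 3 here as names alone and pair nothing across days. Nothing in the labels says that each array held a separate animal, although the design text speaks of independent experiments at each time after surgery. The p-values therefore measure the spread between these samples, which may be technical.

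The deposited scanner tables hold the intensity of each spot on a linear scale, made with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed intensity had been corrected for background by that software, and no normalization between arrays is recorded per the file headers. The array design was annotated on the rat assembly rn4 (RGSCv3.4), per the file headers. The authors also deposited a table of processed values for 24529 features, which is on a log2 scale as judged from the values, with the method of normalization not given in the sources used here. The column medians of that table lay between 7.149 and 7.153, each column correlated best with the scanner values of its own array (r from 0.9936 to 0.9992), and 24484 of its features were gene probes and 45 were control features. Its scale and direction are settled by that comparison, while the step that gave its common centre stays unknown.

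Each array held 1417 control spots, which were left out, and 42136 gene spots of 24684 probes, of which 16245 had 1 spot, 8357 had 3 and 82 had 10. The main values were log2 of the processed intensity minus the 75th percentile of each array. Over all arrays 7348 spots marked as outliers by the scanner software were left out, which left 478 probe values missing, and spots of a probe were averaged. Probes well above background on at least 3 of the 12 arrays were tested, 21062 in all. Gene symbols came from matching RefSeq accessions without versions to a RefSeq gene table of the GRCr8 assembly, which was used for names alone. Of 15323 probes with a coding accession 14274 matched a gene, and of 9361 probes with another identifier 20 matched, so 14294 probes carried 1 symbol, 0 carried several and 10390 carried none. Among tested probes 12722 carried a symbol, for 12354 genes. Where a gene had several probes, the brightest stood for it in the gene lists. Of 277 genes with several tested probes, 4 had probes called in opposite directions at day 7, 6 at day 14 and 4 at day 28 against day 0.

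Group means were fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays, which share 1 estimate of the spread (8 residual and 2.32 prior degrees of freedom), followed by empirical Bayes moderation and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as a call. The comparisons were each graft day against day 0, the graft days against one another, the mean of the 3 graft days against day 0, and an F test over all days. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 read the arrays and drew the plots. A probe not well above background on any array of a group has only a bound there. Its change is given as "at least N-fold", from the mean of the brighter group against the mean of, per array of the dimmer group, the higher of the probe's own value and the lowest value among probes well above background.

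Before the data were examined, 26 gene lists holding 299 genes were fixed: contractile smooth muscle, endothelial, venous identity, arterial identity, adipocyte, mitochondria and fatty acid oxidation, fibrillar matrix, matrix proteases, proliferation, cytokines and adhesion, macrophage, neutrophil, T and NK cell, B and plasma cell, mast cell, erythroid, skeletal muscle, cardiac muscle, Schwann cell, epithelial or gland, TGF-beta signalling, growth factors and receptors, osteochondrogenic, oxidative and hypoxia, coagulation, and named non-coding RNA. They were tested with camera in limma on 12136 genes with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. After the data were seen, 8 lists were written: other skeletal muscle, liver, brain, peripheral neuron and nerve, class II histocompatibility, lysosome and osteoclast, complement, and lung and gland. Their genes are counted from the probe fit and the lists were not tested as sets.

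The genes named were fixed by a rule before the data were examined. Against day 0 they were, among probes with 1 symbol that were called and whose 3 arrays of one day lay beyond the 3 of the other, the 10 largest rises and 10 largest falls with 1 probe per gene and without provisional identifiers, then up to 4 members of each list by smallest adjusted p, then the 3 largest rises and falls of non-coding RNA. Between graft days the numbers were 5 and 5, and 2 members of each called list. The pick of examples among the list members that the rule gives was made after their values were seen. Some genes that the rule gives are not reported here.

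Alternatives planned before the data were examined were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited log2 table, no filter on dim probes, a filter on all arrays (16776 probes), an intensity trend with robust variance, array quality weights, the slide as a fixed block, the mean over all probes of a gene, only the arrays of the days compared, an additional fold change of 2, and each array left out in turn. The slide was read from the scan identity that the file headers give, and a fixed block for it leaves days 7 and 14 linked to day 0 through other days alone. A random block, keeping the outlier spots, leaving out 2 arrays with many non-uniform spots, and values within a slide were added after seeing the data. The fit was tested on simulated data for day 7 against day 0 with 20680 probes: 0%, 12%, 68% and 78% of probes changed by 1.5-fold, 2-fold, 4-fold and 8-fold were recovered (50 probes each), and 3 of 82 calls were false. Of 10 lists of 15 genes shifted by 1 on the log2 scale 10 were called, and of 20 unshifted lists 0 were called by camera. The number of arrays limits the precision. No genome was used here, so probe positions are not given.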

Results

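Gene expression was measured in rat vein on 12 single-colour arrays, 3 for each of 4 days. Day 0 was vein from rats without surgery, and days 7, 14 and 28 were times after a jugular vein had been grafted into the carotid artery, where a vein meets arterial pressure and flow and its wall thickens. The comparisons ask how the graft differed from unoperated vein at each time and how the graft days differed from one another. Of 42136 gene spots per array, between 30301 (71.9%, day 0 replicate 3) and 34817 (82.6%, day 7 replicate 2) were well above background, 0 were saturated, and the 75th percentile of intensity lay between 494 (day 0 replicate 2) and 991 (day 28 replicate 2). Changes are log2 differences ± SE from limma with 3 arrays per day, and the p-values of single genes are adjusted over 21062 probes.

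The first principal component held 48.2% of the variance and set the day 0 arrays, at -83.4, -133 and -200.2, apart from the 9 graft arrays, which lay between 14.2 and 67.7. Pearson correlations of replicates, taken across probes, which are not independent, ran from 0.917 to 0.963 at day 0, from 0.939 to 0.994 at day 7, from 0.979 to 0.993 at day 14 and from 0.976 to 0.991 at day 28. Day 0 replicate 3 and day 7 replicate 3 stood apart, with 460 and 393 spots marked as non-uniform against 2 to 11 on the other arrays. Slide 1 held 2 arrays of day 14 and 2 of day 28, slide 2 held 3 of day 7 and 1 of day 14, slide 3 held 2 of day 0 and 1 of day 28, and slide 4 held 1 of day 0. No slide held both day 7 and day 0, both day 14 and day 0, or both day 28 and day 7. Day 0 replicate 3, alone on slide 4, lay at array position 4, and the arrays of slide 3 lay at positions 1, 2 and 3. Since slides were read from the scan, it may belong to slide 3 and have been scanned apart, which was not checked. Alone on its slide, it adds nothing to the differences between days when the slide is a fixed block.

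Among the largest rises at day 7 were Acan, C1qtnf3, Spp1 and Mmp12, and among the largest falls were Adipoq, Thrsp, RT1-Bb and genes for major urinary proteins. Acan, which encodes the cartilage proteoglycan aggrecan, was not well above background on the day 0 arrays and was at least 146-fold higher at day 7 (adjusted p = 0.000105). C1qtnf3, a secreted protein of the C1q and tumour necrosis factor family, rose by 8.05 ± 0.90 (adjusted p = 0.000141), Spp1, the matrix protein and cytokine osteopontin, by 7.35 ± 0.29 (adjusted p = 7.43e-07), and Mmp12, the macrophage elastase, by 7.14 ± 0.65 (adjusted p = 4.5e-05). Adipoq, the fat cell hormone adiponectin, fell by 8.75 ± 0.44 (adjusted p = 1.52e-06), and Thrsp, a regulator of fatty acid synthesis, was at least 163-fold lower (adjusted p = 2.48e-06).

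Further large rises at day 7 were in Acod1, the itaconate-making enzyme of activated macrophages (at least 50.2-fold), Tnn, the matrix protein tenascin-N (6.76 ± 0.47), Dio3, which inactivates thyroid hormone (6.67 ± 0.52), Slc6a12, a betaine transporter (at least 47.4-fold), Itgam, an integrin of myeloid cells (6.44 ± 0.45), and Nefl, the light neurofilament protein (at least 30.4-fold). RT1-Bb, a chain of a class II histocompatibility molecule, was at least 191-fold lower (adjusted p = 0.0209), a call lost with the random block, with normexp, with array quality weights, without the 2 arrays that had many non-uniform spots, and without day 0 replicate 1 or day 7 replicate 2. With the slide as a fixed block its change shrank to -2.82 (adjusted p = 0.916). Genes for major urinary and odorant-binding proteins, carriers of small lipophilic molecules, were lower as well: Mup4l3 fell by 9.03 ± 0.62, Mup4l4 fell by 8.56 ± 0.88, Obp3 fell by 8.39 ± 0.68 and Mup4l1 fell by 8.38 ± 0.46. Members of that family are near-identical in sequence, so which of them gave the signal is uncertain. Pkhd1l1, a relative of the polycystic kidney protein fibrocystin, fell by 8.10 ± 0.70, Ces1dl1, a carboxylesterase, fell by 7.37 ± 0.90, and Cyp4a3, a fatty acid hydroxylase, was at least 68.5-fold lower; with normexp Ces1dl1 and Cyp4a3 were not called. Among named non-coding RNAs H19, an imprinted transcript of fetal tissue, rose by 3.08 ± 0.83 (adjusted p = 0.0165), a call lost in the fixed block, with only the arrays compared, without day 0 replicate 2 and without the 2 arrays that had many non-uniform spots. Rpph1, the RNA of ribonuclease P, fell by 2.04 ± 0.29 (adjusted p = 0.000586), and Abhd11-as1 fell by 1.17 ± 0.27 (adjusted p = 0.00738) but had a value of 0.53 with normexp.

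Genes of smooth muscle, endothelium, fat cells and mitochondria were lower at day 7 as lists. Of 14 contractile smooth muscle genes 11 fell and 3 did not pass (11 adjusted over the list alone), among them Des, the filament protein desmin (-3.67 ± 0.28), and Mylk, the kinase of the smooth muscle myosin light chain (-3.73 ± 0.52). The median was -2.92, with adjusted p = 9.68e-06 from camera and adjusted p = 0.414 with an estimated correlation. Of 8 endothelial genes 4 fell and 4 did not pass (6 lower adjusted over the list alone), including the junction protein Esam (-3.16 ± 0.26), the sialomucin Emcn (-3.0 ± 0.28) and Nos3, the endothelial nitric oxide synthase (-1.18 ± 0.22). The median was -1.37 (adjusted p = 0.00318; adjusted p = 0.42 with an estimated correlation). Of 8 adipocyte genes 5 fell and 3 did not pass (5 adjusted over the list alone), including the lipid droplet protein Cidec (-6.57 ± 0.29) and the hormone resistin, Retn (-6.89 ± 0.48). The median was -3.45 (adjusted p = 3.75e-05; adjusted p = 0.162 with an estimated correlation). Of 12 genes of mitochondria and fatty acid oxidation 7 fell and 5 did not pass (8 adjusted over the list alone), including Cpt1a, which admits fatty acids to mitochondria (-1.29 ± 0.21). The median was -0.65 (adjusted p = 0.0043; adjusted p = 0.42 with an estimated correlation).

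Genes of immune and blood cells were higher at day 7. Of 16 macrophage genes 14 rose and 2 did not pass (15 adjusted over the list alone), including the lipid-sensing receptor Trem2 (4.72 ± 0.41) and its adaptor Tyrobp (4.62 ± 0.65). The median was 3.01 (adjusted p = 6.88e-06; adjusted p = 0.414 with an estimated correlation). Of 18 genes of cytokines and adhesion 11 rose, 1 fell and 6 did not pass (12 higher and 1 lower adjusted over the list alone). The median was 2.43 (adjusted p = 0.000951; adjusted p = 0.447 with an estimated correlation). Cxcl10, a chemokine for T cells, rose by 4.17 ± 0.38 and Tnf by 4.79 ± 0.77, whereas Sele, the endothelial adhesion molecule E-selectin, fell by 2.00 (adjusted p = 0.00563; chosen after its value was seen). T and NK cell genes rose in 8 of 11 with 3 not passing (8 adjusted over the list alone), including the cytolytic protein Prf1 (2.30 ± 0.23) and the T cell co-receptor Cd4 (3.73 ± 0.46). The median was 1.72 (adjusted p = 0.000951; adjusted p = 0.414 with an estimated correlation). Of 6 neutrophil genes 4 rose and 2 did not pass (4 adjusted over the list alone), including the receptor Csf3r (4.27 ± 0.64). The median was 2.27 (adjusted p = 0.0487; adjusted p = 0.42 with an estimated correlation). Of 4 B and plasma cell genes 3 rose (3 adjusted over the list alone), including the receptor component Cd79b (3.84 ± 0.52). The median was 2.30 (adjusted p = 0.0444; adjusted p = 0.42 with an estimated correlation). Of 4 erythroid genes 3 rose (4 adjusted over the list alone), including Slc4a1, the anion exchanger of red cells (3.68 ± 0.59). The median was 2.50 (adjusted p = 0.0231; adjusted p = 0.42 with an estimated correlation).

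Genes of matrix and its turnover were also higher at day 7. Of 13 fibrillar matrix genes 10 rose and 3 did not pass (10 adjusted over the list alone), including the fibril-starting collagen Col5a1 (3.59 ± 0.28) and periostin, Postn (2.04 ± 0.30). The median was 1.31 (adjusted p = 0.000951; adjusted p = 0.414 with an estimated correlation). Of 14 matrix protease genes 12 rose and 2 did not pass (12 adjusted over the list alone), with a median of 2.68 (adjusted p = 9.68e-06; adjusted p = 0.414 with an estimated correlation), and Mmp13, a collagenase, was at least 28.2-fold higher. Proliferation genes rose in 7 of 15, including the mitotic cyclin Ccnb1 (2.38 ± 0.29), although the list was not called (median 0.86, adjusted p = 0.184). TGF-beta signalling genes rose in 6 of 12 and fell in 1. The median was 1.33 (adjusted p = 0.0733). The 12 skeletal muscle genes had a median change of 0.15 (adjusted p = 0.68), and of 5 cardiac muscle genes 4 fell while Tnnt2, cardiac troponin T, rose by 3.17 ± 0.30.

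In limma 6977 of 21062 probes differed between day 7 and day 0, 3730 higher and 3247 lower, and 5062 of them by at least 2-fold. Without the 2 arrays that had many non-uniform spots 3959 were higher and 4224 lower. The arrays of the days did not overlap for 8394 probes (39.9%), where chance gives 10%. With the slide as a fixed block 55 probes were called (36 higher and 19 lower), and with a random block 5483, while normexp called 3101. Of 72 called genes that the rule names, 72 had the same sign in the fixed block and 7 stayed called: Itgam, Spp1, Cidec, Adipoq, Tnnt2, Slc6a12 and Cybb, a subunit of the phagocyte oxidase. List medians in the fixed block were -2.70 for smooth muscle (adjusted p = 3.43e-05), -1.05 for endothelial (adjusted p = 0.0149), -3.25 for adipocyte (adjusted p = 5.2e-06), 1.17 for fibrillar matrix (adjusted p = 0.00842), 2.36 for matrix protease (adjusted p = 3.71e-05), 2.81 for macrophage (adjusted p = 5.02e-06; 15 genes that entered the list test, with a median of 2.91 without the block) and 1.87 for T and NK cell genes (adjusted p = 0.00256). The block ended the calls of the cytokine (1.81, adjusted p = 0.148), neutrophil (2.22, adjusted p = 0.169), B and plasma cell (1.25, adjusted p = 0.147), erythroid (2.67, adjusted p = 0.0753) and mitochondrial lists (-0.30, adjusted p = 0.0753).

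**Figure D1:**
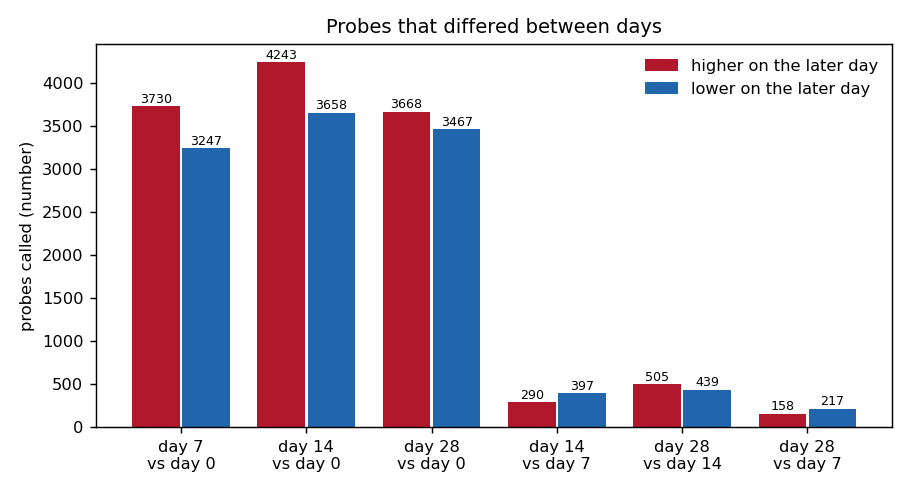
Number of probes called in each comparison of days (bars, number of probes; red, higher on the later day; blue, lower on the later day; 3 arrays per day). Each graft day differed from day 0 at 6977, 7901 or 7135 probes, and graft days differed from one another at 375 to 944.

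Among the largest changes at day 14 were rises of Mmp12, Lilrb2 and Spp1 and falls of Adipoq and Retn. Mmp12 rose by 8.16 ± 0.65 (adjusted p = 1.62e-05), Lilrb2, an inhibitory receptor of myeloid cells, by 7.12 ± 0.59 (adjusted p = 1.87e-05), Spp1 by 6.99 ± 0.29 (adjusted p = 6.5e-07) and Atp6v0d2, a subunit of the proton pump of osteoclasts and macrophages, by 6.75 ± 0.32 (adjusted p = 8.69e-07). Il10ra, the receptor chain for interleukin-10, was at least 58.6-fold higher (adjusted p = 9.83e-07). Adipoq fell by 8.25 ± 0.44 (adjusted p = 1.81e-06) and Retn fell by 7.45 ± 0.48. Ntf3, the neurotrophin-3 gene, was at least 189-fold lower (adjusted p = 1.45e-05).

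Other large rises at day 14 were in Dio3 (7.11 ± 0.52), Slc6a12 (at least 51.5-fold) and A2m, alpha-2-macroglobulin (6.61 ± 0.54). Fgg, the fibrinogen gamma chain, rose at least 40.5-fold (adjusted p = 5.18e-05). A2m stood at 1.21 to 2.36 at days 7 and 28, Fgg near background. Msln, a surface protein of mesothelium, rose by 6.86 ± 1.72 (adjusted p = 0.0106), with day 0 arrays at 2.47, -3.25 and -6.63. Large falls were also in Pkhd1l1 (at least 464-fold lower), Pcp4l1 (-8.22 ± 0.60), the neural transcription factor Pou3f3 (-7.82 ± 0.61), the motor protein Myo5b (at least 153-fold lower), and Mup4l4 (-7.32 ± 0.88) and Obp3 (-7.32 ± 0.68), where the family member is again uncertain. H19 rose by 5.21 ± 0.83 (adjusted p = 0.000851), Rpph1 fell by 1.77 ± 0.29 (adjusted p = 0.00103), and Abhd11-as1 fell by 1.27 ± 0.27 (adjusted p = 0.00425). All these calls were lost in the fixed block (adjusted p = 0.056, 0.133 and 0.121), and that of Abhd11-as1 was also lost with normexp.

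Of 14 contractile smooth muscle genes 11 fell at day 14 and 3 did not pass (11 adjusted over the list alone), including Lmod1, which nucleates smooth muscle actin filaments (-4.68 ± 0.35), and Mylk (-4.61 ± 0.52). The median was -3.14 (adjusted p = 5.45e-06; adjusted p = 0.473 with an estimated correlation). Endothelial genes fell in 4 of 8 with 4 not passing (4 lower and 1 higher adjusted over the list alone), including Esam (-2.72 ± 0.26) and Nos3 (-0.94 ± 0.22). The median was -0.87 (adjusted p = 0.0327; adjusted p = 0.664 with an estimated correlation). Adipocyte genes fell in 6 of 8 with 2 not passing (6 adjusted over the list alone), including Cidec (-5.79 ± 0.29). The median was -2.67 (adjusted p = 0.000537; adjusted p = 0.33 with an estimated correlation).

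Macrophage genes rose in 15 of 16 at day 14 with 1 not passing (15 adjusted over the list alone), including Trem2 (5.87 ± 0.41) and Gpnmb, a glycoprotein of lipid-laden macrophages (4.24 ± 0.54). The median was 3.47 (adjusted p = 5.45e-06; adjusted p = 0.473 with an estimated correlation). T and NK cell genes rose in 9 of 11 with 2 not passing (9 adjusted over the list alone), including Cd4 (4.70 ± 0.46) and the protease granzyme B, Gzmb (4.38 ± 0.70). The median was 2.03 (adjusted p = 0.00212; adjusted p = 0.473 with an estimated correlation). Of 18 cytokine and adhesion genes 10 rose, 1 fell and 7 did not pass (12 higher and 1 lower adjusted over the list alone). The median was 2.25 (adjusted p = 0.00545; adjusted p = 0.732 with an estimated correlation). Ccl3, a chemokine for monocytes, rose by 5.68 ± 0.85, and Sele again fell by 2.07 (adjusted p = 0.00397). Proliferation genes rose in 9 of 15 with 6 not passing (10 adjusted over the list alone), including cyclin A2, Ccna2 (3.93 ± 0.60), and the mitotic kinesin Kif20a (3.68 ± 0.47). The median was 1.32 (adjusted p = 0.015; adjusted p = 0.473 with an estimated correlation). Fibrillar matrix genes rose in 8 of 13 with 5 not passing (10 higher and 1 lower adjusted over the list alone), including Col5a1 (3.6 ± 0.28). The median was 1.37 (adjusted p = 0.0136; adjusted p = 0.584 with an estimated correlation). Matrix protease genes rose in 12 of 14 with 2 not passing (12 adjusted over the list alone), including urokinase, Plau (2.22 ± 0.24). The median was 2.72 (adjusted p = 2.04e-05; adjusted p = 0.473 with an estimated correlation).

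Skeletal muscle genes varied between the arrays of day 14. The list medians were 2.10, -1.20 and 2.72 on replicates 1 to 3, against -2.04, -1.60 and -1.67 at day 0. Of its 12 genes 5 rose and 7 did not pass (5 adjusted over the list alone). The fast troponin Tnnc2 (4.96 ± 1.22) and myosin light chain Myl1 (4.59 ± 1.27) lost their calls in the fixed block. Myl1 also did so without day 14 replicate 1 or 3. The list was not called (median 1.79, adjusted p = 0.153) except in the fixed block (4.79, adjusted p = 0.0205; adjusted p = 0.952 with an estimated correlation and no block). Osteochondrogenic genes rose in 3 of 8 and fell in 1 (median 1.18, adjusted p = 0.221).

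In limma 7901 probes differed between day 14 and day 0, 4243 higher and 3658 lower, and 5794 by at least 2-fold. Without the 2 arrays that had many non-uniform spots 4577 were higher and 5034 lower. The arrays did not overlap for 10743 probes (51.0%; 10% by chance). Normexp called 3529. With the slide as a fixed block 1034 probes were called, and of 70 called genes that the rule names 70 had the same sign and 38 stayed called. In that block the list medians were -2.85 for smooth muscle (adjusted p = 1.56e-05), -2.33 for adipocyte (adjusted p = 0.000269), 2.33 for matrix protease (adjusted p = 0.000104), 1.25 for proliferation (adjusted p = 0.0291), 3.26 for macrophage (adjusted p = 1.39e-05) and 1.70 for T and NK cell genes (adjusted p = 0.0057), while the calls of endothelial (-0.91, adjusted p = 0.111), fibrillar matrix (1.02, adjusted p = 0.0574) and cytokine genes (1.61, adjusted p = 0.26) ended.

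**Figure D2:**
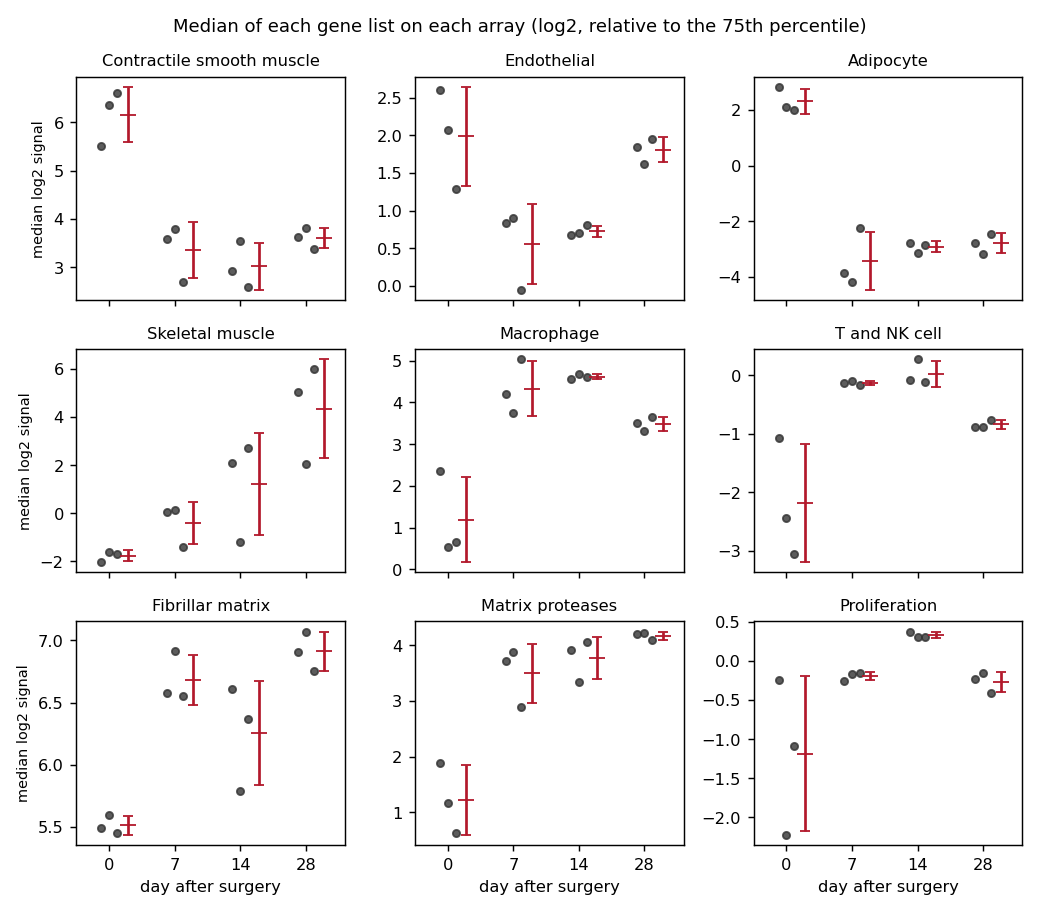
Median log2 signal of 9 gene lists on each array, relative to the 75th percentile of the array, by day after surgery (grey points, arrays; red, mean ± SD of 3 arrays; each panel has its own vertical axis). Skeletal muscle medians were 5.01, 2.03 and 5.98 at day 28 against -2.04, -1.60 and -1.67 at day 0.

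At day 28 the skeletal muscle list was higher, and Acan, Kera and C1qtnf3 were among the largest rises. Acan was at least 273-fold higher (adjusted p = 9.1e-05), Kera, the corneal proteoglycan keratocan, at least 86.2-fold higher (adjusted p = 4.03e-05), and C1qtnf3 rose by 8.71 ± 0.90 (adjusted p = 0.000136). Myh4, a fast myosin heavy chain, rose by 9.12 ± 1.63 (adjusted p = 0.00231). Of 12 skeletal muscle genes 11 rose and 1 did not pass (11 adjusted over the list alone). The median was 5.97 (adjusted p = 0.000201; adjusted p = 0.568 with an estimated correlation). The list medians were 5.01, 2.03 and 5.98 on the day 28 arrays, so day 28 replicate 2 lay below the others.

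Other large rises at day 28 were in muscle genes: the sarcomere protein Myot (at least 114-fold, adjusted p = 0.0014), Tnnc2 (8.14 ± 1.22), the calcineurin-binding Myoz1 (8.11 ± 1.35), the fast troponin Tnni2 (7.98 ± 1.23) and Myl1 (7.78 ± 1.27); Dio3 rose by 7.49 ± 0.52. Large falls were in Mup4l4 (-9.39 ± 0.88), Mup4l3 (-9.20 ± 0.62), Obp3 (-9.19 ± 0.68) and Mup4l1 (-8.74 ± 0.46), with the member uncertain, and in Cyp4a3 (at least 92.2-fold lower). Igfals, a carrier of insulin-like growth factor, fell by 9.38 ± 1.85 (adjusted p = 0.00389) and Psd by 7.62 ± 1.02 (adjusted p = 0.000522). The thyroid transcription factor Foxe1 fell by 7.57 ± 1.18 (adjusted p = 0.00123) and the serine protease hepsin, Hpn, by 7.17 ± 1.57 (adjusted p = 0.00659). The calls of Igfals, Psd, Foxe1 and Hpn were lost in the fixed block (adjusted p = 0.127, 0.052, 0.0828 and 0.175). Igfals also varied within days, at 6.48, 1.37 and 8.65 at day 7 and 3.53, 7.00 and 0.98 at day 14. H19 rose by 5.63 ± 0.83 (adjusted p = 0.000876), Rpph1 fell by 2.53 ± 0.29 (adjusted p = 0.000242), and RT1-T24-2 fell by 1.81 ± 0.51 (adjusted p = 0.021), a call lost with normexp, in the fixed block (adjusted p = 0.0677), with only the arrays compared, and without day 0 replicate 2 or day 28 replicate 1 or 2.

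Contractile smooth muscle genes fell in 10 of 14 at day 28, with 1 higher and 3 not passing (11 lower and 1 higher adjusted over the list alone). The median was -2.59 (adjusted p = 7.68e-05; adjusted p = 0.527 with an estimated correlation). Mylk fell by 4.32 ± 0.52 and Des fell by 2.62 ± 0.28, while the gene that rose was Pln, the calcium pump inhibitor phospholamban (4.36, adjusted p = 0.0417; chosen after its value was seen). Adipocyte genes fell in 5 of 8 with 3 not passing (5 adjusted over the list alone), including Cidec (-5.36 ± 0.29) and Adipoq (-4.96 ± 0.44). The median was -3.24 (adjusted p = 7.68e-05; adjusted p = 0.184 with an estimated correlation). Endothelial genes had a median of -0.19 (adjusted p = 0.547), with 1 higher, 2 lower and 5 not passing. Cdh5, VE-cadherin, rose by 0.86 ± 0.25 (adjusted p = 0.0226), whereas Esam fell by 1.69 ± 0.26 and Emcn fell by 1.64 ± 0.28. All these calls were lost in the fixed block (adjusted p = 0.0555, 0.102 and 0.14). The call of Cdh5 was also lost with normexp, with array quality weights, with only the arrays compared and without the 2 arrays that had many non-uniform spots. It was lost as well without day 0 replicate 3 or day 28 replicate 1 or 3.

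Matrix protease genes rose in 11 of 14 at day 28 with 3 not passing (12 adjusted over the list alone), including Mmp12 (7.46 ± 0.65), Mmp3 (5.61 ± 0.59) and Mmp13 (at least 79.5-fold). The median was 2.67 (adjusted p = 2.19e-05; adjusted p = 0.527 with an estimated correlation). Fibrillar matrix genes rose in 8 of 13 with 5 not passing (8 adjusted over the list alone), including Col5a1 (3.62 ± 0.28) and Cthrc1, a protein of injured arteries (4.73 ± 0.74). The median was 1.66 (adjusted p = 0.000519; adjusted p = 0.527 with an estimated correlation). TGF-beta signalling genes rose in 7 of 12 with 5 not passing (8 adjusted over the list alone), including Ltbp2 (6.29 ± 0.94) and Tgfb1 (3.19 ± 0.36). The median was 1.75 (adjusted p = 0.00363; adjusted p = 0.568 with an estimated correlation). Osteochondrogenic genes rose in 3 of 8 with 5 not passing (3 adjusted over the list alone), with a median of 1.04 (adjusted p = 0.0497; adjusted p = 0.527 with an estimated correlation): Acan, Spp1 (6.89 ± 0.29) and Bmp2 (0.65 ± 0.19). The call of Bmp2 was lost with normexp, in the fixed block, with array quality weights, with only the arrays compared, and when day 0 replicate 1 or 3 or day 28 replicate 1, 2 or 3 was left out.

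Macrophage genes rose in 13 of 16 at day 28 with 3 not passing (14 adjusted over the list alone), including Trem2 (5.04 ± 0.41) and the lysozyme Lyz2 (3.29 ± 0.57). The median was 2.20 (adjusted p = 4.2e-05; adjusted p = 0.568 with an estimated correlation). Cytokine and adhesion genes rose in 7 of 18 with 11 not passing (8 adjusted over the list alone), including the monocyte chemokine Ccl2 (3.27 ± 0.65) and the adhesion molecule Vcam1 (2.00 ± 0.41). The median was 1.39 (adjusted p = 0.00578; adjusted p = 0.649 with an estimated correlation). T and NK cell genes rose in 5 of 11 with 6 not passing (7 adjusted over the list alone), including Gzmb (3.26 ± 0.70) and Cd4 (3.00 ± 0.46). The median was 1.14 (adjusted p = 0.0462; adjusted p = 0.568 with an estimated correlation). Of 15 proliferation genes 7 rose and 2 fell (median 0.73, adjusted p = 0.458).

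In limma 7135 probes differed between day 28 and day 0, 3668 higher and 3467 lower, and 5199 by at least 2-fold. The split was 4254 higher and 2951 lower with median centring, 4080 and 5226 without the 2 arrays that had many non-uniform spots, and 3983 and 4480 with array quality weights. The prevailing direction thus depended on the setting. The arrays did not overlap for 10189 probes (48.4%; 10% by chance). The fixed block rests on slide 3, with 1 array of day 28 and 2 of day 0, and called 1363 probes, while normexp called 2594. Within that slide alone limma called 0 (3367 at an unadjusted p under 0.05). Of 74 called genes that the rule names 44 stayed called in the block. List medians in the block were -2.19 for smooth muscle (adjusted p = 0.00024), -3.0 for adipocyte (adjusted p = 6.3e-05), 1.34 for fibrillar matrix (adjusted p = 0.00102), 2.27 for matrix protease (adjusted p = 1.37e-05), 2.07 for macrophage (adjusted p = 1.37e-05), 7.36 for skeletal muscle (adjusted p = 1.37e-05) and 1.37 for TGF-beta genes (adjusted p = 0.0303), while cytokine (0.77, adjusted p = 0.14), T and NK cell (0.68, adjusted p = 0.104) and osteochondrogenic genes (0.51, adjusted p = 0.152) were no longer called.

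**Figure D3:**
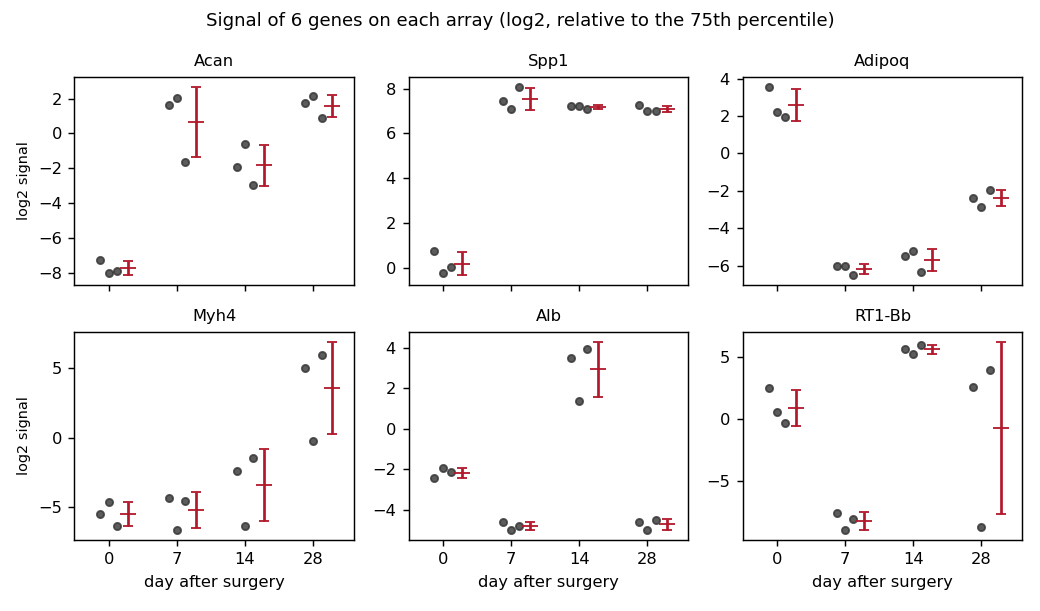
Log2 signal of Acan, Spp1, Adipoq, Myh4, Alb and RT1-Bb on each array, relative to the 75th percentile of the array, by day after surgery (grey points, arrays; red, mean ± SD of 3 arrays; each panel has its own vertical axis). Alb lay at 3.49, 1.38 and 3.95 on the day 14 arrays and between -5.01 and -1.95 on the others.

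Between day 7 and day 14, Fabp1, Alb and Fgg were among the largest rises, and Chgb and Nefm were among the largest falls. Fabp1, the liver fatty acid-binding protein, was at least 103-fold higher at day 14 (adjusted p = 0.00015), albumin, Alb, rose by 7.73 ± 0.53 (adjusted p = 0.000169), Fgg was at least 45.5-fold and Mug1l1, a murinoglobulin-type gene, at least 21.2-fold higher. RT1-Bb was at least 5062-fold higher (adjusted p = 0.0179), a call lost with normexp, in the fixed block (adjusted p = 0.261), and when day 14 replicate 1, 2 or 3 or day 7 replicate 1 or 2 was left out. The vesicle protein Chgb fell by 6.24 ± 0.81 (adjusted p = 0.0028), the neurofilament gene Nefm was at least 51.7-fold lower (adjusted p = 0.000508), the calcium pump gene Atp2b2 at least 60.8-fold, the calcium-binding Calb1 at least 36.7-fold and Serpinb11 at least 34.7-fold lower. B and plasma cell genes fell in 2 of 4 (3 adjusted over the list alone; median -2.25, adjusted p = 0.00134; adjusted p = 0.682 with an estimated correlation), with Cd79b at -2.82 ± 0.52. Erythroid genes fell in 1 of 4, the haem enzyme Alas2 (-2.00 ± 0.45), with 4 lower adjusted over the list alone (median -1.75, adjusted p = 0.00289; adjusted p = 0.682 with an estimated correlation). Proliferation genes had 1 of 15 higher, the ubiquitin enzyme Ube2c (0.95 ± 0.19), with 1 adjusted over the list alone (median 0.55, adjusted p = 0.0351; adjusted p = 0.682 with an estimated correlation). The 12 skeletal muscle genes, not passing singly, had a median of 1.84 (adjusted p = 0.0457; adjusted p = 0.713 with an estimated correlation). In all 687 probes differed (290 higher and 397 lower; 619 by 2-fold; 454 higher and 345 lower with only the arrays compared), and arrays did not overlap for 6984 (33.2%; 10% by chance). The fixed block called 28, normexp 55, and the arrays without the 2 that had many non-uniform spots 2426. Of 17 called genes that the rule names 3 stayed called in the fixed block, Fabp1, Alb and Mug1l1. Chgb (adjusted p = 0.221), Nefm (adjusted p = 0.0853), Atp2b2, Calb1, Serpinb11, Cd79b, Alas2 and Ube2c lost their calls there, while 4 calls stayed with normexp and 9 whichever array was left out. In the fixed block the medians were -2.36 for B and plasma cell genes (adjusted p = 0.000685), -1.76 for erythroid genes (adjusted p = 0.0125), 0.45 for proliferation (adjusted p = 0.0154) and 2.80 for skeletal muscle (adjusted p = 0.00349). Within slide 2 alone, which holds 1 array of day 14, limma called 0 probes (1408 unadjusted).

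Between day 14 and day 28 Fabp1, Alb and Fgg were among the largest falls, and Kera, Myh4 and Ntf3 were among the largest rises. Fabp1 was at least 139-fold lower (adjusted p = 0.000166), Alb fell by 7.65 ± 0.53 (adjusted p = 0.000249), and Fgg, Mug1 and Mug1l1 were at least 61.2-fold, 29.1-fold and 28.5-fold lower. Kera rose by 6.54 ± 0.66 (adjusted p = 0.00123), Ntf3 was at least 26.6-fold and Pkhd1l1 at least 22.9-fold higher, the muscle calcium buffer Pvalb rose by 5.79 ± 1.15 and Myh4 by 7.05 ± 1.63 (adjusted p = 0.0402; lost with normexp, in the fixed block, and when day 14 replicate 1, 2 or 3, day 28 replicate 1 or 3 or day 7 replicate 1 was left out). Adipoq rose by 3.29 ± 0.44 (adjusted p = 0.00458). The 10 called lists each had adjusted p = 0.435 with an estimated correlation, except macrophage genes with adjusted p = 0.595 with an estimated correlation. Smooth muscle genes rose in 1 of 14 (4 adjusted over the list alone), Lmod1 by 1.59 ± 0.35, with a median of 0.75 (adjusted p = 0.00282). The 8 endothelial genes did not pass singly (6 higher adjusted over the list alone) and had a median of 1.04 (adjusted p = 0.00221). Arterial identity genes rose in 1 of 7 (2 adjusted over the list alone), the Notch ligand Jag1 by 1.37 ± 0.33, with a median of 0.80 (adjusted p = 0.0287). B and plasma cell genes rose in 2 of 4 (3 adjusted over the list alone; median 1.87, adjusted p = 0.0101), and skeletal muscle genes in 1 of 12 (4 adjusted over the list alone; median 3.18, adjusted p = 0.00025). TGF-beta signalling genes rose in 2 of 12 (3 adjusted over the list alone), the inhibitors Smad6 by 2.00 ± 0.33 and Smad7 by 1.19 ± 0.23, with a median of 1.40 (adjusted p = 0.00341). Proliferation genes fell in 1 of 15 (1 adjusted over the list alone), Ube2c at -1.29 ± 0.19, with a median of -0.63 (adjusted p = 0.00317), and T and NK cell genes in 1 of 11 (2 adjusted over the list alone), Nkg7 at -1.42 ± 0.32, with a median of -0.82 (adjusted p = 0.00341). The 6 neutrophil genes did not pass singly (3 lower adjusted over the list alone; median -2.17, adjusted p = 0.0287), nor did the 16 macrophage genes, singly or over the list alone (median -0.92, adjusted p = 0.0101).

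In all 944 probes differed between day 28 and day 14 (505 higher and 439 lower; 783 by 2-fold), and arrays did not overlap for 10631 (50.5%; 10% by chance). Median centring gave 758 higher and 341 lower, normexp called 135, and without the 2 arrays that had many non-uniform spots 4799 were called (2399 higher and 2400 lower). The fixed block, which rests on slide 1 with 2 arrays of each day, called 124 (47 higher and 77 lower), and within slide 1 alone limma called 2141. Of 26 called genes that the rule names 7 stayed called in the fixed block: Kera, Ntf3, Fabp1, Alb, Fgg, Mug1 and Mug1l1. Adipoq (adjusted p = 0.0604), Pkhd1l1, Pvalb, Myh4, Lmod1 (adjusted p = 0.159), Jag1, Smad6, Smad7, Nkg7 and Ube2c were among those that lost their calls there. With normexp 5 stayed called, and 12 stayed whichever array was left out. List medians in the block were 0.80 for smooth muscle (adjusted p = 0.00742), 0.85 for endothelial (adjusted p = 0.00784), -0.69 for proliferation (adjusted p = 0.00742), -1.06 for macrophage (adjusted p = 0.0204), -0.91 for T and NK cell (adjusted p = 0.00742), 1.93 for B and plasma cell (adjusted p = 0.00742), 2.92 for skeletal muscle (adjusted p = 0.00479) and 1.51 for TGF-beta genes (adjusted p = 0.00742), while arterial (0.62, adjusted p = 0.0989) and neutrophil genes (-2.58, adjusted p = 0.0989) were not called. Schwann cell genes, not called without the block (0.42, adjusted p = 0.131), had a median of 1.12 in it (adjusted p = 0.0109). With an estimated correlation and no block they had adjusted p = 0.692.

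Between day 7 and day 28 the skeletal muscle and endothelial lists were higher. Myh4 rose by 8.83 ± 1.63 (adjusted p = 0.028), Myoz1 by 6.89 ± 1.35, the muscle carbonic anhydrase Car3 by 6.54 ± 1.17 and the fast-fibre actinin Actn3 by 6.33 ± 1.29, and Myf6, a myogenic transcription factor, was at least 23.3-fold higher. Falls were in Psd (-5.07 ± 1.02), Serpinb11 (-4.41 ± 0.85), the kinase Sik1 (-3.99 ± 0.64), the secreted Prok2 (at least 15.3-fold lower) and the olfactory receptor Or52z12 (at least 8.04-fold lower, adjusted p = 0.00203). Adipoq rose by 3.79 ± 0.44 (adjusted p = 0.00473), and Adipoq and Or52z12 were the named genes called whichever array was left out. Skeletal muscle genes rose in 3 of 12 (11 adjusted over the list alone). The median was 5.08 (adjusted p = 6.74e-09; adjusted p = 0.292 with an estimated correlation; list medians 0.05, 0.14 and -1.40 on the day 7 arrays). Endothelial genes rose in 2 of 8 (7 adjusted over the list alone), Esam by 1.47 ± 0.26 and Emcn by 1.36 ± 0.28. The median was 1.36 (adjusted p = 2.78e-06; adjusted p = 0.292 with an estimated correlation). Arterial identity genes rose in 1 of 7 (6 adjusted over the list alone), the gap junction gene Gja5 by 2.19 ± 0.41. The median was 1.36 (adjusted p = 0.000926; adjusted p = 0.292 with an estimated correlation). T and NK cell genes fell in 1 of 11 (3 adjusted over the list alone), Prf1 at -1.19 ± 0.23. The median was -0.67 (adjusted p = 0.003; adjusted p = 0.292 with an estimated correlation). Of lists whose members did not pass singly, neutrophil genes had a median of -2.35 (6 genes, 4 adjusted over the list alone; adjusted p = 0.000937; adjusted p = 0.292 with an estimated correlation), erythroid genes -1.28 (4 genes; adjusted p = 0.0269; adjusted p = 0.499 with an estimated correlation) and mitochondrial genes 0.42 (12 genes, 4 adjusted over the list alone; adjusted p = 0.003; adjusted p = 0.447 with an estimated correlation).

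In all 375 probes differed between day 28 and day 7 (158 higher and 217 lower; 353 by 2-fold), and arrays did not overlap for 7552 (35.9%; 10% by chance). The split was 302 higher and 182 lower with median centring, 22 and 70 with normexp, and 228 and 197 with the deposited log2 values. No slide held both days, and without the 2 arrays that had many non-uniform spots 934 were called. The fixed block, through other days, called 0 in limma (626 at an unadjusted p under 0.05; 115 called with a random block). Of 20 called genes that the rule names 3 stayed called with the random block, Or52z12, Adipoq and Thbd, and 5 with normexp, while the fixed block ended all these calls. List medians in the fixed block were 1.17 for endothelial (adjusted p = 6.32e-06), 1.13 for arterial (adjusted p = 0.00592), -2.53 for neutrophil (adjusted p = 0.00592), -0.81 for T and NK cell (adjusted p = 0.00592), 6.03 for skeletal muscle (adjusted p = 3.29e-10) and 0.23 for mitochondrial genes (adjusted p = 0.0249), while erythroid genes (-1.12, adjusted p = 0.124) were not called. Lists called in the block and not without it were TGF-beta signalling (0.97, adjusted p = 0.0194; without it 0.80, adjusted p = 0.0573), adipocyte (0.48, adjusted p = 0.023; without it 0.54, adjusted p = 0.0784) and Schwann cell genes (1.1, adjusted p = 0.0189; without it 0.90, adjusted p = 0.162). With an estimated correlation and no block these had adjusted p = 0.644, 0.43 and 0.644.

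Over the mean of the 3 graft days, matrix protease genes rose in 12 of 14 (median 2.80), macrophage genes in 15 of 16 (2.88), T and NK cell genes in 9 of 11 (1.60, adjusted p = 0.00293) and fibrillar matrix genes in 10 of 13 (1.5, adjusted p = 0.00187), while smooth muscle genes fell in 11 of 14 (-2.79) and adipocyte genes in 6 of 8 (-3.20, adjusted p = 0.000143; adjusted p = 0.228 with an estimated correlation). Smooth muscle, protease and macrophage lists each had adjusted p = 9.66e-06, and with T and NK cell and fibrillar matrix lists each had adjusted p = 0.47 with an estimated correlation. Cytokine and adhesion genes rose in 14 of 18 and fell in 1 (1.82, adjusted p = 0.00187; adjusted p = 0.618 with an estimated correlation), skeletal muscle genes rose in 6 of 12 (3.05, adjusted p = 0.0404; adjusted p = 0.624 with an estimated correlation), endothelial genes fell in 4 of 8 (-0.78) and mitochondrial genes fell in 5 and rose in 1 of 12 (-0.39), these last each with adjusted p = 0.0498 and adjusted p = 0.618 with an estimated correlation. Adjusted over the list alone the counts of these lists were the same, apart from 13 matrix protease genes. In limma 9091 probes differed between the mean of the grafts and day 0 (4732 higher and 4359 lower; 5698 by 2-fold; 4765 higher and 5616 lower without the 2 arrays that had many non-uniform spots), and 8528 differed over all days in the F test. With the slide as a fixed block these counts were 608 and 811.

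The graft days shared many of their differences from day 0. Of 21062 probes 2394 were higher at all 3 graft days, 1933 were lower at all 3, and 10 were called at all 3 in mixed directions. Days 7 and 14 shared 2908 higher and 2552 lower probes, where independent lists of those sizes would share 751.4 and 563.9, and 29 were called in opposite directions. Days 7 and 28 shared 2712 and 2251 (649.6 and 534.5 for independent lists; 9 opposite), and days 14 and 28 shared 2784 and 2340 (738.9 and 602.1; 15 opposite). Correlations of the fold changes across probes, which are not independent replicates, were 0.835, 0.842 and 0.83 for these pairs. In 100 simulations of unchanged groups that shared a simulated control group they were 0.501, 0.503 and 0.502. With the spread of each probe taken from limma, the simulations gave 0 shared calls. Covariances were 1.64, 1.58 and 1.67, against 0.103 or 0.104 in the simulations. The simulated noise was drawn separately for each probe, so it left out differences between whole control arrays. The simulations therefore cannot tell how much the shared controls add. The 3 controls cannot be split into parts of at least 2 arrays, so part of the excess may come from the shared controls.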

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

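The tests of the slide, of brain RNA, of peripheral nerve and of a sequence variant were chosen after the result was seen. The test of other splits of the arrays was chosen before. The tests of attached muscle, of liver RNA and of antigen-presenting cells were chosen before their own result was seen. They use gene lists written after the data were seen, so they were not fixed independently of the patterns they address. The counts, fixed lists and single genes below differed between graft days, that is, the change from day 0 was not the same at different times after surgery, in limma or camera. The lists of other muscle, liver, brain, peripheral nerve and class II genes were written after the data were seen and were not tested as sets.

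Skeletal muscle genes were higher at day 28 than at day 7, by a median of 5.08 over 12 genes, and the arrays of a day varied: list medians were 5.01, 2.03 and 5.98 at day 28, 2.10, -1.20 and 2.72 at day 14, and 0.05, 0.14 and -1.40 at day 7. The slide as sole source is argued against, since day 14 replicates 3 and 2, on the same slide, differed by 4.12. With the slide as a fixed block the median was 6.03 (adjusted p = 3.29e-10 from camera with the preset correlation). With an estimated correlation and no block camera gave adjusted p = 0.292. The block links day 7 to day 28 through the day 14 arrays, which themselves varied. It therefore cannot part the slide from the muscle content of the samples. Of 16 measured genes on a separate list of abundant muscle transcripts, 81.2% were higher by 1 or more at day 28, a share that attached skeletal muscle in the samples would give, and the fast myosin gene Myh4 lay at 5.04, -0.23 and 5.96 on the day 28 arrays. Of those 16 genes, 11 were well above background on the 3 day 0 arrays, as were most gene spots, so muscle RNA there stays open. A gain that belongs to the time after surgery stays open, as untested. Other values were also lowest on day 28 replicate 2. Endothelial list medians were 1.85, 1.625 and 1.95 at day 28 (0.67, 0.70 and 0.81 at day 14). Arterial identity medians were 1.45, 0.50 and 1.80 (0.35, 0.30 and 0.50 at day 14). H19 lay at 4.51, 3.12 and 5.38 (4.10, 3.15 and 4.49 at day 14). At day 14 the endothelial median was not lowest on replicate 2. Whether attached tissue added to these values was not tested.

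Single genes known from liver, Alb, Fabp1 and Fgg, were higher at day 14 than at day 7, with Alb at 3.49, 1.38 and 3.95 against -4.59, -5.0 and -4.78, and single genes known from neurons, Chgb, Nefl and Nefm, were lower, while limma called 2 of 25 genes of the liver list higher and 1 lower, and 4 of 20 of the brain list lower. The slide as the source of the Alb difference is argued against, since Alb on day 14 replicate 1 lay 8.08 above the highest day 7 array of the same slide. Peripheral nerve in the day 7 samples stays open: the median difference over 10 genes of neurons and nerve was -0.033, but that list leaves out Nefl, Nefm, Chgb and Mbp, which differed, and so excludes nothing. RNA from liver in the day 14 samples (52% of 25 liver genes higher by 1 or more at day 14) and RNA from brain in the day 7 samples (50% of 20 brain genes higher by 1 or more at day 7) stay open, since both shares lie between those that would have decided. A change of these genes in the graft itself could not be tested separately.

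RT1-Bb lay near background on the day 7 arrays (-7.61, -8.98 and -8.05) and on day 28 replicate 2 (-8.72), against 2.62 and 3.94 on the other day 28 arrays and 5.69, 5.23 and 5.97 at day 14. Fewer antigen-presenting cells are argued against, since 10 other class II genes differed by a median of -0.61 between day 7 and day 14, and the slide is argued against, since RT1-Bb on day 14 replicate 1 lay 13.3 above the highest day 7 array of the same slide. On day 28 replicate 2 the other class II genes differed by a median of -0.26 from the other day 28 arrays, which a sequence variant under the probe in some of the animals would give. That may be the source of the pattern, as a hypothesis, since it was found and tested on the same arrays. A dependence on the time after surgery alone would not give 1 low array at day 28, and other differences between animals stay untested.

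Counts of probes that differed between graft days were 687 for day 14 against day 7, 944 for day 28 against day 14 and 375 for day 28 against day 7. In each of the 6 comparisons of days 1 of the 10 splits of the 6 arrays, the real one, called as many probes, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 6977 and 19 for day 7, 7901 and 0 for day 14 and 7135 and 1 for day 28 against day 0, then 687 and 0, 944 and 1, and 375 and 4 between graft days. For the mean of the grafts 1 of 100 splits, the real one, reached 9091, with 7987 as the highest other. For the F test 1 of 100 reached 8528, with 6677 as the highest other. A random assignment of the arrays is thus unlikely for these. Days were grouped by slide and the splits ignored slides, so they cannot tell a difference of days from one of slides. Other splits thus also call many probes, which points to a structure of the samples, in which grafts and day 0 stand far apart.

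Between day 14 and day 7 the median differences of gene lists were 0.55 for proliferation, -2.25 for B and plasma cells, 1.84 for skeletal muscle and -1.75 for erythroid genes. Between day 28 and day 14 they were 0.75 for smooth muscle, 1.04 for endothelial, 0.80 for arterial identity, -0.63 for proliferation, -0.91 for macrophage (15 genes that entered the list test), -2.17 for neutrophil, -0.82 for T and NK cell, 1.87 for B and plasma cell, 3.18 for skeletal muscle and 1.40 for TGF-beta signalling genes. Between day 28 and day 7 they were 1.36 for endothelial, 1.36 for arterial identity, -2.35 for neutrophil, -0.67 for T and NK cell, 5.08 for skeletal muscle, -1.28 for erythroid and 0.42 for mitochondrial genes. With an estimated correlation camera called 0 lists in each of these comparisons (1, 0 and 2 at an unadjusted p under 0.05), and the smallest adjusted p values were 0.682, 0.435 and 0.292.

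Single genes that differed between day 14 and day 7, as log2 differences, included Alb (7.73), Atp6v0d2 (1.51), Tnnt2 (1.5), Cxcl10 (-1.72), Alas2 (-2.00), Cd79b (-2.82), the neural genes Pou3f3 (-3.11), Mbp (-4.06) and Chgb (-6.24), and Pcp4l1 (-3.37). Where a day lay at background the difference is a bound: at least 12.31 for RT1-Bb, 6.69 for Fabp1, 5.51 for Fgg, 4.43 for Mug1, 4.40 for Mug1l1 and 2.96 for Cyp4a3, and at most -2.81 for Or52z12, -5.12 for Nefl, -5.12 for Serpinb11, -5.20 for Calb1, -5.69 for Nefm and -5.92 for Atp2b2. With the slide as a fixed block 3 of 17 calls of named genes stayed, those of Fabp1, Alb and Mug1l1.

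Between day 28 and day 14 genes that were higher included the matrix genes Kera (6.54) and Mmp13 (2.76), the secreted C1qtnf3 (4.03), Adipoq (3.29) and Bmp4 (3.25), the muscle genes Pvalb (5.79) and Lmod1 (1.59), and genes of endothelium and its anticoagulant surface, Sele (2.13), Vcam1 (1.74), Thbd (1.62), Procr (1.40) and Jag1 (1.37). The inhibitors Smad6 (2.00) and Smad7 (1.19), the extracellular superoxide dismutase Sod3 (2.05) and the oxidase Nox4 (1.22) were higher too, with bounds of at least 4.73 for Ntf3, 4.52 for Pkhd1l1 and 2.14 for Pdk4. Among the largest falls were those of Fabp1, Alb, Fgg, Mug1 and Mug1l1, and others lower at day 28 included Foxe1 (-4.87), Mup4l1 (-2.59), Lilrb2 (-2.40), Pck1 (-1.84), Il10ra (-1.69), Nkg7 (-1.42), Plau (-1.35) and Ube2c (-1.29). With the slide as a fixed block 7 of 26 calls of named genes stayed, those of Kera, Ntf3, Fabp1, Alb, Fgg, Mug1 and Mug1l1.

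Between day 28 and day 7 the genes that were higher included Adipoq (3.79), Thbd (1.59) and Procr (1.33), the muscle genes Myh4 (8.83), Myoz1 (6.89), Car3 (6.54) and Actn3 (6.33), and the endothelial genes Gja5 (2.19), Flt4 (1.74), Esam (1.47) and Emcn (1.36), with bounds of at least 4.54 for Myf6 and 1.75 for Thrsp. Lower genes included Or52z12, Serpinb11 (-4.41), Cxcl10 (-1.92), Psd (-5.07), Sik1 (-3.99), the neutrophil collagenase Mmp8 (-3.78) and Prf1 (-1.19), with a bound of at most -3.94 for Prok2. With normexp Flt4 turned to -0.0083. The calls of Gja5, Flt4, Esam and Emcn were lost with a random block (adjusted p = 0.0757, 0.0757, 0.0584 and 0.0922) and with the fixed block (adjusted p = 0.995 for each). Of 20 calls of named genes the random block kept 3, those of Or52z12, Adipoq and Thbd, and the fixed block ended all.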

How the results depend on the processing

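The random block, keeping outlier spots, leaving out the 2 arrays with many non-uniform spots (day 0 replicate 3 and day 7 replicate 3) and the tests within a slide were added after seeing the data, and normexp used the median signal of each spot, since the planned mean signal was not used here. No paired analysis was possible because the labels give every array the same replicate number. Of 279 calls of named genes the deposited log2 values kept 277, quantile normalization 278, median centring 276, normexp 204, the random block 258, the fixed block 99 and only the compared arrays 251, and of 52 list calls these settings kept 50, 47, 49, 49, 38 and 49, leaving aside the random block, which camera does not take. Values of named genes that turned were Abhd11-as1 at day 7 (0.53, adjusted p = 0.541) and Flt4 for day 28 against day 7 (-0.0083, adjusted p = 0.993), both with normexp. Normexp called 3101, 3529 and 2594 probes at days 7, 14 and 28 against day 0, 55 for day 14 against day 7, 135 for day 28 against day 14, 92 for day 28 against day 7, 4113 for the mean of grafts and 3276 in the F test, with 7 lists for day 14 against day 7 and 1566 probes in the overlap of graft days. With it the median change of all probes was 0.44 at day 7, -0.16 at day 28, -0.37 for day 14 against day 7, -0.14 for day 28 against day 14 and -0.48 for day 28 against day 7 (-0.026, 0.0095, 0.052, -0.085 and 0.014 without it), and with median centring it was 0.11 at day 28 and 0.16 for day 28 against day 7. In the same order the fixed block called 55, 1034, 1363, 28, 124 and 0 (626 unadjusted, by limma), 608 and 811, with 7 lists at day 7 and an overlap of 55; the random block called 115 for day 28 against day 7. With only the compared arrays the counts were 2888 at day 7, 4635 at day 28, 6352 for day 28 against day 14, 178 for day 28 against day 7 and 2059 in the overlap. Array weights, whose fit gave a warning, called 10670, 16424 and 13439 between graft days, with 9 lists for day 14 against day 7. Without the 2 arrays these counts were 2426, 4799 and 934. Probes well above background on all arrays gave 365 for day 14 against day 7, and a 2-fold change in addition left 5698 for the mean of grafts. With an estimated correlation camera called 0 lists at day 7, 0 at day 14, 0 at day 28, 0 in each comparison of graft days and 0 for the mean (1, 1, 1, 1, 0, 2 and 1 at an unadjusted p under 0.05 in the order above), where fry called 19, 12, 13, 0, 7, 7 and 17. The cause was not tested for any of these changes.

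With each array left out in turn, calls ranged from 5024 to 7826 at day 7, from 5721 to 8825 at day 14, from 4572 (without day 28 replicate 1) to 8337 at day 28, from 225 (without day 14 replicate 1) to 1263 (without day 7 replicate 3) for day 14 against day 7, from 163 (without day 28 replicate 1) to 2270 (without day 7 replicate 3) for day 28 against day 14, from 34 (without day 28 replicate 1) to 643 (without day 0 replicate 3) for day 28 against day 7, from 7852 to 10010 for the mean and from 6339 to 9396 in the F test. Lists called ranged over 10 to 12, 8 to 10, 8 to 10, 2 to 4 (2 without day 14 replicate 3), 9 to 11, 6 to 11 (11 without day 0 replicate 1 or day 7 replicate 2) and 7 to 10, and the overlap from 3207 to 5411. Other arrays that moved a count by over 1.5 times were, for day 14 against day 7, day 0 replicate 3 (1209), day 7 replicates 1 (240) and 2 (297), day 14 replicates 2 (414) and 3 (260) and day 28 replicate 1 (451). For day 28 against day 14 they were day 0 replicates 1 (1688) and 3 (1970), day 7 replicate 1 (537), day 14 replicates 1 (167), 2 (307) and 3 (261) and day 28 replicates 2 (320) and 3 (503), and for day 28 against day 7 they were day 7 replicate 1 (50), day 14 replicate 1 (184) and day 28 replicate 3 (86). Signal over background limits the dim probes, which have bounds in place of folds.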

Other observations

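The 8 lists described first were written after the data were seen, and their genes were chosen then. Of 10 measured genes of antigen presentation by class II molecules, a list that leaves out RT1-Bb (at least 191-fold lower at day 7), 8 rose at day 7, 8 at day 14 and 7 at day 28 against day 0, with medians of 3.64, 4.26 and 3.00. Cd74, the class II invariant chain, rose by 4.56, 4.98 and 4.30 on those days (adjusted p = 0.000402, 0.000183 and 0.000735), and Ciita, the transactivator of class II genes, by 3.72, 4.02 and 2.91 (adjusted p = 2.93e-05, 1.53e-05 and 0.000177). Genes of lysosomes and osteoclasts rose in 8, 9 and 8 of 9 measured, with medians of 1.33, 1.98 and 1.45, including the proton pump subunit Atp6v0d2 (5.24, 6.75 and 5.56; adjusted p = 4.77e-06, 8.69e-07 and 5.25e-06) and the lysosomal channel Mcoln3 (4.39, 5.42 and 4.10). Complement genes rose in 6, 6 and 5 of 13, with medians of 1.74, 1.77 and 1.45, including the receptor C3ar1 (3.34, 3.38 and 1.83).

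Genes of lung and gland fell in 5 of 10 on each graft day, with medians of -1.41, -1.04 and -1.54. Sftpc, a lung surfactant protein, stood at -6.39, -5.53 and -6.04 (adjusted p = 1.18e-05, 2.12e-05 and 2.35e-05), the airway secretory protein Scgb1a1 at -4.31, -3.63 and -3.49, and the prolactin receptor Prlr at -4.71, -4.79 and -5.21 (adjusted p = 4.69e-06, 3.21e-06 and 3.4e-06). Of 16 other skeletal muscle genes 1 rose and 2 fell at day 7, 2 rose and 2 fell at day 14, and 10 rose and 2 fell at day 28, with medians of -0.06, 1.62 and 3.89, or 1.17 and 3.51 on the later days with dim genes at their bounds. Of 25 liver genes 3 rose and 7 fell at day 7, 9 rose and 3 fell at day 14, and 4 rose and 9 fell at day 28, with medians of -0.32, 1.16 and -0.69 (-0.42 at day 28 with bounds). The liver genes Hpd, of tyrosine breakdown, and Hrg, a plasma glycoprotein, rose from day 7 to day 14 by 3.39 (adjusted p = 0.00899) and 2.85 (adjusted p = 0.00546). Of 20 brain genes 8 rose and 2 fell at day 7, 3 rose and 4 fell at day 14, and 3 rose and 4 fell at day 28, with medians of 0.73, -0.32 and -0.06, and Camk2a (-3.25), Gad1 (-4.29), Nrgn (-3.13) and Cplx1 (-4.41) fell from day 7 to day 14. Of 10 genes of peripheral neurons and nerve 1 rose and 2 fell at day 7, 3 fell at day 14 and 1 fell at day 28, with medians of -0.53, -0.54 and -0.09.

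Per day 0 array 71.91% to 81.15% of spots were well above background. On all 3 so were 9 of 10 class II, 8 of 9 lysosome, 13 of 13 complement and 8 of 10 lung and gland. So were 11 of 16 other skeletal muscle, 15 of 25 liver, 19 of 20 brain and 8 of 10 peripheral nerve genes. Of the genes written on the peripheral nerve list 2 also stood on the fixed Schwann cell list, and the other added lists shared 0 with the fixed lists.

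Fixed lists that were not called in any comparison of days without the slide as a block had the following medians at days 7, 14 and 28 against day 0. Venous identity genes stood at -0.25, 0.70 and 1.1 (adjusted p = 0.617, 0.987 and 0.725), mast cell genes at -1.02, -0.78 and -1.15 (adjusted p = 0.529, 0.832 and 0.725), cardiac muscle genes at -1.63, -2.09 and -2.33 (adjusted p = 0.356, 0.488 and 0.415) and Schwann cell genes at -0.70, -0.45 and -0.03 (adjusted p = 0.706, 0.782 and 0.725), and the last were called in the fixed block between day 28 and days 14 and 7. Epithelial or gland genes stood at 0.42, 0.76 and 0.85 (adjusted p = 0.912, 0.782 and 0.725), growth factors and receptors at 0.22, 0.40 and 0.76 (adjusted p = 0.68, 0.723 and 0.415; 0.11 at day 14 with a dim gene at its bound), and oxidative and hypoxia genes at 0.49, 0.07 and 0.07 (adjusted p = 0.617, 0.987 and 0.547). Coagulation genes stood at 0.42, 0.40 and 0.29 (adjusted p = 0.857, 0.832 and 0.791) and named non-coding RNAs at -0.12, -0.23 and -0.21 (adjusted p = 0.706, 0.898 and 0.725). Members that changed within them included Thbd, thrombomodulin, at -2.16 ± 0.22 and Procr, the protein C receptor, at -2.66 ± 0.28 at day 7, Sod3 at -2.72 ± 0.50 and Hmox1, haem oxygenase 1, at 2.74 ± 0.63 at day 14, and Fgfr1 at 2.82 ± 0.39 and Pdgfrb at 1.73 ± 0.34 at day 28.

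Median, mean and test differed in sign for several lists. The median was positive and the test downward for venous identity at day 14 (mean -0.02), for epithelial genes at day 7 (mean 0.53), for coagulation at days 7 (mean 0.27) and 14 (mean 0.11) and over the mean of grafts (median 0.37, mean 0.40), and for oxidative genes at day 14 (mean 0.36). Named non-coding RNAs had negative medians and positive means (0.31, 1.07 and 0.96) with a downward test on each graft day. Schwann cell genes had a median of -0.03 and a mean of 0.57 with an upward test at day 28, and between day 14 and day 7 a median of 0.20 and a mean of -0.14 with a downward test. Between day 28 and day 14 matrix proteases (median 0.04, mean -0.08, downward) and mast cell genes (-0.28 and -0.08, upward) differed in sign. Between day 28 and day 7 matrix proteases (0.30 and -0.08, upward) did.

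Shares of called probes by kind of transcript were as follows. Of 13626 tested coding probes 36.1%, 40.9% and 35.4% were called at days 7, 14 and 28 against day 0, and of 7436 other probes 27.6%, 31.4% and 31.1% were called. Between graft days the shares were 3.15% and 3.47% for day 14 against day 7, 4.42% and 4.60% for day 28 against day 14, and 1.95% and 1.48% for day 28 against day 7. No difference between the kinds was tested.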
